A study of Microlunatus phosphovorus with 2 samples.

How the data were processed

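RNA was sequenced from 2 samplings of a culture of Microlunatus phosphovorus strain JN459, a bacterium that stores phosphate as polyphosphate. Per the labels' protocols, the cells were grown with air in a sequencing batch reactor (SBR, a tank run in repeated cycles) at 28 °C for 74 h, after which aerobic and anaerobic stages alternated. One library was made at 86 h and is labelled aerobic, and 1 library was made at 92 h and is labelled anaerobic. RNA was treated with DNase before the cDNA libraries were prepared, per the labels' protocols. A step that removes ribosomal RNA is not given in the sources used here, nor are the aligner, the counting tool, the genome build or the annotation.

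The authors deposited 1 table of 5040 features for the whole series. Each feature has an identifier that is a locus tag with the ending .t01 or .r01, a value for each library, and the authors' log2 fold change, p-value and q-value. The table does not pair identifiers with gene names, products or positions, and no reference was used here. The 29 gene lists fixed before the data were examined (polyphosphate enzymes, phosphate transport, respiration and others) rest on names and products, so 0 of them were matched and no list result is given. The rule for named features also asked for products. From its parts on the largest fold and on the 5 highest levels of each library, the feature with the largest fold and the most abundant feature were named in each direction, 2 per direction.

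The unit of the deposited values is named neither in the labels nor in the header. They were taken as RPKM (reads per kilobase of gene per 1000000 reads) made by the authors, which is an inference from the values. The sums of 1273248 and 1734881 exceed what CPM or TPM allow. Among features with both values above 0, the ratio of the 2 libraries was a fraction of small whole numbers times 1 common factor in 382 features. This count is for terms up to 40, within a relative tolerance of 1e-05, at the best of many factors scanned. The median over the factors scanned was 45 features, at a wider tolerance. Gene length cancels in this ratio. The count therefore points to whole reads scaled by 1 factor per library, and cannot tell RPKM from other scalings of reads. The best factor makes the 92 h library 1.08 times as deep as the 86 h library. A common step was fitted to the features ending in .t01 and was taken as 3 bases. With it, 133 of 359 of these features had a length in whole bases, within 0.02 of a base. Of the 133 lengths, 104 (78.2%) were multiples of 3, but that share is largely set by taking the step as 3 bases. It is therefore no support for the unit. On this scale, 8 of 23 features ending in .r01 had whole lengths, which were 36, 41, 73, 73, 76, 76, 77 and 117 bases. A length found this way is too short by a whole factor where the reads of both libraries share that factor. The inferred depth was about 11678000 reads or fragments at 86 h and 12655000 at 92 h. These depths are inferences from the values and rest on the fitted step being 3 bases. Counts per feature were not used because most lengths stay unknown. At these depths a gene of 1000 bases at 10 RPKM would hold 117 reads at 86 h and 127 at 92 h. The lowest values above 0 were 1.02 and 1.04 RPKM, and 12 features listed at 0 in both libraries still have a log2 fold change in the authors' deposited table, so values below 1 appear as 0.

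The authors' deposited log2 column equals the log2 ratio of the 92 h value to the 86 h value, within 1e-06, in all but 2 of the 5006 features with both values above 0. The deposited q-values differed by at most 0.885% from Benjamini-Hochberg adjustment of the deposited p-values. In 13 features the deposited log2, p-value and q-value are all 0, and these were treated as not tested. The test behind the p-values is not given in the sources used here.

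From the RPKM values, the fold of each feature was computed as log2((RPKM at 92 h + 1)/(RPKM at 86 h + 1)), with a pseudocount of 1. This scale understates the change of low features. Features with a mean of at least 10 RPKM over both libraries entered the comparison, and a feature counted as higher or lower with a log2 fold of at least 1 in size, that is 2-fold. With 1 library per condition there is no spread between replicates, so the conditions were not tested against each other. The p-values printed in the closing section are the authors' deposited ones, or come from a normal model of the log ratio fitted to RPKM only to rebuild them, and they are no evidence on the conditions. The design, this floor, the size rule and the alternatives (3 other scalings, 2 other pseudocounts, 2 other floors, 2 other sizes, and the deposited log2 column) were fixed before the data were examined. The trimmed mean scaling left out 30% of the log ratios at each end and 5% of the mean levels at each end. Features were also ordered by tag number, and the correlation of folds between near tags was set against 1000 shuffles of the order.

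The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data of 5040 features for the comparison of 92 h with 86 h. There, 200 of 200 features changed 4-fold were recovered, 0 unchanged features were called, and the inferred depth was within 0.00329% of the depth set. The simulated reads held counting noise only, with no differences between cultures. Levels were capped so that no feature dominated a library, and every length was a multiple of 3 bases. These rates of error therefore do not carry over to the real libraries.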

Results

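Expression was measured by RNA sequencing in Microlunatus phosphovorus JN459 at 2 times in a sequencing batch reactor. The study's title sets the question of how genes of polyphosphate metabolism are expressed when phosphorus is accumulated and when it is released. In polyphosphate-accumulating bacteria, phosphate is taken up with air and released without it. There was 1 aerobic library (86 h) and 1 anaerobic library (92 h), sampled 6 h apart. The conditions differ in oxygen supply and in time, and these cannot be separated with 1 library each. All values below are the authors' deposited values, taken as RPKM, each from a single library and so without a replicate error. Of 5040 features, 5014 were above 0 at 86 h and 5008 at 92 h, and 24 were listed at 0 in both. The median feature was at 81.7 RPKM at 86 h, with an interquartile range of 30.1 to 201 RPKM. At 92 h the median was 42.8 RPKM, with an interquartile range of 17.7 to 125 RPKM. The inferred depths were about 11678000 reads or fragments at 86 h and 12655000 at 92 h.

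The transcript pool differed widely between the aerobic and the anaerobic library. Of the 4663 features with a mean of at least 10 RPKM, 1987 (42.6%) were at least 2-fold lower at 92 h, 602 (12.9%) were at least 2-fold higher, and 2074 (44.5%) were neither. The median log2 fold was -0.72. Scaling the libraries to a median ratio of 1, a shift of 0.73 on the log2 scale, gave 1189 higher and 1195 lower features among the 4814 that reached the floor after scaling. The share of lower features among those that differed was 76.7% on the deposited scale and 50.1% on the median scale, where the centring itself sets a share near an even split. Differences of at least 8-fold were seen in both directions on either scale. On the deposited scale, 91 features were at least 8-fold higher and 342 at least 8-fold lower at 92 h, while on the median scale 189 of the 4814 were higher and 134 lower. Which direction held more features therefore depends on the scaling, for large folds too, and the counts have no replicate check. Across features, the 2 libraries had a Pearson correlation of 0.58 on log2(RPKM + 1) and a Spearman correlation of 0.59, where features are not independent replicates.

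**Figure D1:**
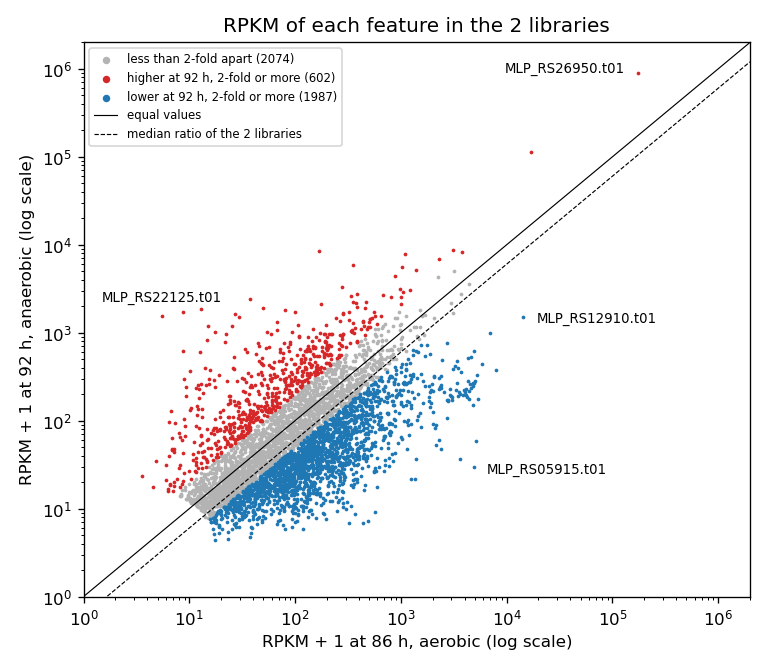
RPKM + 1 of each of the 4663 features with a mean of at least 10 RPKM at 86 h (aerobic, x axis, log scale) and at 92 h (anaerobic, y axis, log scale), 1 library each. Each point is a feature, red where it was at least 2-fold higher at 92 h (602 features), blue where at least 2-fold lower (1987) and grey otherwise (2074); the solid line marks equal values and the dashed line the median ratio, and the 4 named features carry their identifiers.

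The most abundant feature in both libraries was MLP_RS26950.t01. Its level was 173951 RPKM at 86 h and 903538 RPKM at 92 h, which is 5.19-fold higher in the anaerobic library. It made up 13.7% of the sum of RPKM at 86 h and 52.1% at 92 h. These are shares of RPKM, which weight short genes more than shares of reads do. The 10 most abundant features together held 19.4% of the RPKM sum at 86 h and 61.9% at 92 h. After scaling to the median ratio, the log2 fold of MLP_RS26950.t01 was 3.11 in place of 2.38.

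The largest fold upwards belonged to MLP_RS22125.t01, which was at 4.50 RPKM in the aerobic library and 1568 RPKM in the anaerobic library (log2 fold 8.15). Among the 4663 features that reached the floor, it moved from rank 4660 by level to rank 48. A feature this low at 86 h reaches the floor only through its 92 h value. The rank at 86 h is therefore largely set by the floor, and features low in both libraries are not ranked. The low value at 86 h corresponds to an inferred 52.6 reads per 1000 bases of gene, and with pseudocounts of 0.1 and 5 the log2 fold was 8.41 and 7.37. Under the 3 other scalings it lay between 8.78 and 8.92. It was 1 of 11 features below 10 RPKM at 86 h and at 100 RPKM or more at 92 h.

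The largest fold downwards belonged to MLP_RS05915.t01, which was at 4863 RPKM in the aerobic library and 28.7 RPKM in the anaerobic library (log2 fold -7.35). Among the features that reached the floor, it ranked 13 by level at 86 h and 3105 at 92 h. The most abundant of the features that were lower at 92 h was MLP_RS12910.t01, with 14327 RPKM at 86 h and 1524 RPKM at 92 h (log2 fold -3.23). Both stayed lower under each scaling tried, with log2 folds of -6.61 or less and -2.47 or less. In the other direction to the 11 features above, 30 features were at 100 RPKM or more at 86 h and below 10 RPKM at 92 h. Both counts are on the deposited scale and were not taken under the other scalings, which would move them.

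The abundant transcripts were largely exchanged between the 2 libraries. Of the 100 most abundant features at 86 h, 83 were at least 2-fold lower at 92 h and 5 were at least 2-fold higher, with a median log2 fold of -3.38. Of the 100 most abundant features at 92 h, 71 were at least 2-fold higher than at 86 h and 1 was at least 2-fold lower, with a median log2 fold of 1.61. The lists shared 17 features, where 2.14 would be shared by independent lists of this length. A list chosen for a high level in 1 library leans towards that library, so these directions are in part set by the choice. After a shift of all folds by the median ratio, 79 of the first list were lower and 86 of the second were higher. At 86 h, 171 features were at 1000 RPKM or more, against 101 at 92 h, on the deposited scale only.

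The folds were spread more widely among features with a high mean over both libraries than among those with a low mean. In the tenth of features with the lowest mean, up to 19.5 RPKM, the median log2 fold was -0.40 with an SD of 0.81 across 467 features, and 24 were higher and 95 lower. In the tenth with the highest mean, 411 RPKM or more, the median was -0.56 with an SD of 2.55 across 467 features, and 125 were higher and 204 lower. The pseudocount narrows the folds of low features. The lowest median, -1.04, was in the bin from 59.8 to 83.3 RPKM.

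Features whose identifiers end in .r01 were a small class of 53, of which 49 reached the floor. Of these, 28 were at least 2-fold lower at 92 h and 4 at least 2-fold higher, with a median log2 fold of -1.34 and an interquartile range of -2.27 to -0.29. Their median was 76.9 RPKM at 86 h and 29.2 RPKM at 92 h. The 4614 features ending in .t01 that reached the floor had a median log2 fold of -0.71, with 598 higher and 1959 lower. The difference between the classes was not tested.

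**Figure D2:**
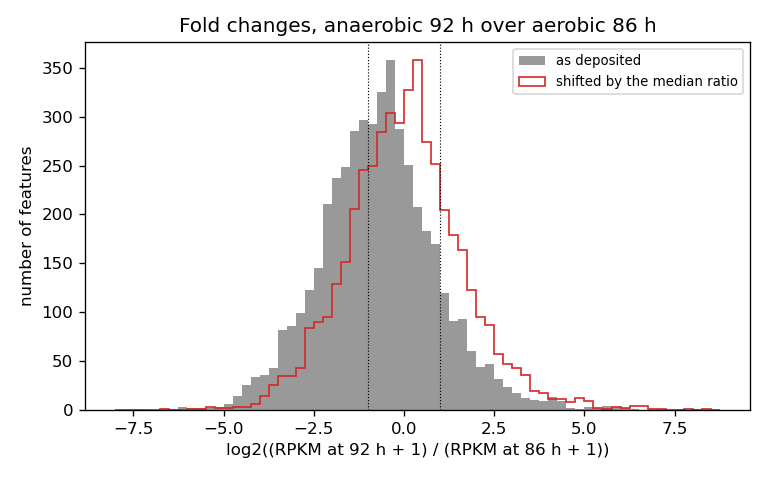
Number of features (y axis) by log2((RPKM at 92 h + 1)/(RPKM at 86 h + 1)) (x axis), in bins of 0.25, for the 4663 features with a mean of at least 10 RPKM. The grey bars are the deposited scale, centred on a median of -0.72, the red outline is the same folds shifted by 0.73 to the median ratio, and the dotted lines mark 2-fold in each direction.

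The authors' deposited table compares the same 2 libraries by a test that is not named. Of its 5027 tested features, 3701 (73.6%) had a q-value under 0.05, of which 717 had a log2 fold above 0 and 2984 below 0. With a log2 fold of at least 1 in size as well, the authors' deposited table has 577 higher and 2037 lower features. These q-values compare 2 libraries and do not measure the spread between cultures. Of 69 features with a mean of at least 100 RPKM and a log2 ratio within 0.1 of 0, 65 also had a q-value under 0.05. At that mean level, the 9 features with a deposited p above 0.9 had a median log2 fold of 0.46. The split may therefore lean towards lower features, and the share of 73.6% is not a share of changed features.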

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

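The counts of 602 higher and 1987 lower features depended on the scaling and on the size rule. Higher and lower features numbered 1189 and 1195 with median-of-ratios scaling, 1219 and 1170 with trimmed mean scaling, and 1078 and 1303 when the total was taken without the 10 most abundant features of each library. These scalings come before the floor, so 4814, 4820 and 4801 features reached it in place of 4663. With a log2 fold of at least 1.5 there were 391 higher and 1405 lower features, and with at least 2 there were 238 higher and 920 lower, fewer by construction. Settings added after seeing the data gave 480 higher and 459 lower for a log2 fold of at least 2 with median-of-ratios scaling. For a log2 fold of at least 3 they gave 91 and 342 as deposited, and 189 and 134 with median-of-ratios scaling. The other settings kept both counts within 1.5 times: pseudocounts of 0.1 and 5, no floor, a floor of 50 RPKM, the deposited log2 column, and 3 further settings chosen after seeing the data (without the division by depth, without the features ending in .r01, and with the 92 h value of 2 features as their deposited log2 implies). The 4 named features have folds larger than any shift between the scalings, so the scalings could not turn their direction. Depth limits low features most, and with 1 library per condition no library could be left out. No paired analysis was possible because there is 1 library per condition and no test. The alternatives for the gene lists (membership and matching of random lists) were not run, since no list could be matched.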

Other observations

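The tests named here were chosen after the results were seen. Features next to each other in the order of tag numbers tended to change alike. Only features that reached the floor were ordered, so tags missing from the order were bridged. If tag numbers follow the order of genes along the chromosome, which was not checked against a genome, these are neighbouring genes. With features ordered by tag number, the longest run of consecutive features at least 2-fold lower at 92 h held 26, with a median log2 fold of -4.16 and medians of 4057 RPKM at 86 h and 216 RPKM at 92 h. The longest such run in 1000 shuffles of the order held 16. The longest run of features at least 2-fold higher held 15, with a median log2 fold of 3.66 and medians of 16.6 RPKM at 86 h and 132 RPKM at 92 h, and the longest in shuffles held 8. After the shift to the median ratio the longest runs held 24 lower and 16 higher features, against 11 and 11 in shuffles. The feature with the largest fold upwards, MLP_RS22125.t01, lay in a run of 4 higher features with log2 folds from 3.51 to 8.15 and a median of 6.58. The feature with the largest fold downwards, MLP_RS05915.t01, lay in a run of 16 lower features with log2 folds from -7.35 to -1.41 and a median of -2.60. The longest runs in the shuffles held 8 higher and 16 lower features, so neither of these 2 runs was longer than all shuffles gave. After the shift to the median ratio, members such as MLP_RS05855.t01 (log2 fold -1.41 before it) are less than 2-fold lower, so the run of 16 is broken.

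A hypothesis for these runs is that neighbouring genes change together, as genes of one transcription unit would. Across features, the correlation of log2 folds between adjacent features in this order was 0.53, above the highest of 1000 shuffles (0.044), and it was 0.30 at 2 places and 0.10 at 5 places. It was still above the highest shuffle at 10 places (0.083 against 0.042) and just above it at 50 places (0.045 against 0.043), but not at 20 or 100 places, and 1 transcription unit would not be expected to reach that far. A fold that depends on level, with neighbours at like levels, is argued against as the whole cause, since the correlation within 10 bins of mean level was 0.50. Reads shared between adjoining genes are argued against as the whole cause too, since features 3 places apart still had a correlation of 0.18, above the highest shuffle (0.040). Whether the runs are operons stays open, because no annotation was used and tag order stands in for position.

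The excess of lower over higher features at 92 h is a second pattern with a technical side. Reads taken by the most abundant feature could lower all others alike. MLP_RS26950.t01 would need a length of 499 bases for its reads alone to give the median ratio of 0.60, below the 1107 bases that its RPKM allows at most, and its length is not known here. The effect of this feature, a fall of many transcripts without oxygen, and the later sampling time therefore cannot be told apart.

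The third pattern concerns the deposited p-values, which were low even for features with nearly equal RPKM. Of 69 features with a mean of at least 100 RPKM and a log2 ratio within 0.1 of 0, 65 had a q-value under 0.05 in the authors' deposited table. A test on reads with depths as library sizes would give its highest p-values near a log2 of 0, but among all features with a mean of at least 100 RPKM, the 9 with p above 0.9 had log2 folds from 0.42 to 0.47 with a median of 0.46, which argues against it. A candidate explanation is that the RPKM values were tested as if they were counts, with their sums as library sizes: the log2 ratio of the sums is 0.45, and a normal model of the log ratio built that way differed from the deposited p by a median of 0.0054 in log10 units over 4894 features. With the no-change point at a log2 of 0 the same model differed by a median of 3.58. Under this reading, the large feature MLP_RS26950.t01 also shifts the point that counts as no change, so calls of features with small folds would depend on it.

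In 2 features, singled out after their values were seen, the listed values and the deposited log2 column point in opposite directions. MLP_RS08475.t01 is listed at 286.8 RPKM at 86 h and 507.3 RPKM at 92 h, a log2 ratio of 0.82, while the authors' deposited table gives a log2 fold of -2.39. That log2 with the listed 86 h value gives 54.6076 RPKM at 92 h. MLP_RS02595.t01 is listed at 255.1 RPKM at 86 h and 476.8 RPKM at 92 h, a log2 ratio of 0.90, while the deposited log2 fold is -0.37 and gives 197.107 RPKM at 92 h. Both values at 92 h come out at 6 digits, like the other entries of the table, while the 86 h values that the listed 92 h values would need do not. The normal model, used here only to see which values the deposited p-values were made from, gave p-values of 2.87e-55 and 1.52e-09 for these values at 92 h, beside deposited p-values of 3.04e-55 and 1.56e-09, and 2.87e-04 and 2.66e-05 for the listed values. With the values at 92 h that the deposited log2 gives, the count of lower features was 1988 in place of 1987.

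The 13 features with a deposited log2, p-value and q-value of 0 would pass any q-value threshold if they were not left out, and 12 of them are listed at 0 in both libraries.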
